A study of Mus musculus with 18 samples.

How the data were processed

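Raw gene counts were used as deposited by the authors. Per the labels, RNA from 5x10E5 cells per sample went through a TruSeq RNA v2 kit, single-end reads of 50 bases were sequenced on a HiSeq4000, and reads were aligned with STAR to mm10. The versions, the counting tool, the annotation and the use of strand were not given in the sources used here. The count table held 23337 gene symbols in 21 columns. Of these, 18 columns were matched to samples by name, and 3 columns that matched no sample of the series were left out. Group membership came from the labels alone. The columns carried a running number but no replicate number, and that number was not used. In the 18 libraries 5267 genes had no count, and totals ran from 5257601 to 7122093. Every pair of libraries of a day was checked for being copies of each other on genes with at least 20 counts, and the chi-square over degrees of freedom ran from 2.206 to 9.232.

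Genes were tested with edgeR 4.0.16 in R 4.3.3. filterByExpr on the 6 days (minimum count 10) kept 13116 genes, TMM factors scaled the libraries, and a model with a mean per day was fitted with robust dispersion estimates (estimateDisp, glmQLFit) and tested by quasi-likelihood F tests (glmQLFTest) with 12 residual degrees of freedom. All 18 libraries shared the estimate of spread. The common dispersion was 0.006838, a biological coefficient of variation of 8.27%. Comparisons were an F test across days, D15 against D5, the mean of D8, D10 and D15 against the mean of D5, D6 and D7, and the 5 steps between neighbouring harvests. P-values were adjusted by Benjamini-Hochberg over the genes tested, and genes at an adjusted p under 0.05 were called. The SE was the log2 fold change without shrinkage divided by the square root of F, and was not given for genes without a count on a day. Log2 CPM used a prior count of 2. Peak day was the day of the highest mean log2 CPM among genes called across days with a range of at least 1.

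Genes were named by a rule. A fixed set of genes was examined in every comparison. The 10 largest rises and falls for D15 against D5 and between the stages, and the 4 largest for each step, were taken among called genes with a mean log2 CPM of at least 2, values without overlap and a symbol other than a predicted model. The 5 largest F across days and up to 4 members with the smallest p of each described list were added. Members that were exceptions to the direction of their list were named after the values were seen. For genes without a count in a group, lower bounds set that group at 3 counts and took the count of the other group as exact. For 1 to 3 counts, ratios carry a 95% counting interval from the binomial distribution.

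The 28 gene lists had 379 entries, of which 375 were found under their own symbol, 3 under an older symbol and 1 (Muc16) not at all. Lists were tested by camera (limma 3.58.1) on voom values with a preset correlation of 0.01, adjusted over the lists of a comparison. Beside this stood camera with an estimated correlation and fry. Of the symbols, 20756 matched a RefSeq GRCm38.p6 table. Clca1, Aldh1a2, Osr1, Cdh1, Disp1, Dll4, Eno1, Gjc1, Gpi1, Hcn4, Igf2bp1, Ldb3 and Sp5 are also older symbols of other genes, and which gene was meant was not given. Coordinates are from GENCODE M21. The share of unique 50-base stretches per gene was computed against the transcripts of that release, and genes under 80% are given as uncertain. Exons of the named genes Acadvl, Aspn, Bmp4, Bmp5, Bnc1, Ckm, Col3a1, Col6a6, Cryab, Des, Dll4, Eng, Eomes, Esrra, Fam123c, Foxf1a, Foxm1, Gas1, Gata6, Gja5, Gli1, Gli3, Gpi1, Hadha, Hand2, Has2, Hhip, Hmga2, Igf2bp1, Igfbp7, Islr, L1cam, Lef1, Lin28a, Lox, Mef2a, Mef2d, Mtap2, Myh6, Myh7, Myl2, Myl3, Myl4, Mylk, Ncam1, Ndufa4l2, Nr2f2, Nrarp, Pdgfra, Pou5f1, Rubie, Runx1, S100a4, Sall4, Slc2a1, Smtn, Sox17, Spry1, Tagln, Tbx18, Tfcp2l1, Tpi1, Trim71, Txnip, Ube2c and Wnt5a overlap exons of another gene on either strand, so their counts may hold reads of that gene.

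Alternatives were RLE and upper quartile factors, DESeq2 1.42.0, limma-voom, no filter, a filter of 1 CPM in 9 libraries, fits of the compared days alone, a model with the stages as the only groups, a fold threshold of 2, and each library left out in turn. Within-day relations between lists were tested by 46656 permutations within days. Tables and figures were made with Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

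The tests were tested on simulated data with the dispersions and library sizes of the real genes, in which 200 of 13116 genes were changed. Changes were at most 4-fold, as many up as down, from a mean per gene that was otherwise equal on all days. The real comparisons called 24.2% to 88.9% of genes, so the check does not cover scaling or false calls where most genes change. For D15 against D5, edgeR recovered 61.2% of 1.5-fold, 82.1% of 2-fold and 98.5% of 4-fold changes. From D8 to D10 it recovered 47.8%, 77.6% and 92.4%. False calls were 4.17% of edgeR calls for D15 against D5, 9.14% across days, 6.37% between the stages, 7.43% for D5 to D6, 4.76% for D6 to D7, 7.78% for D7 to D8, 5.84% for D8 to D10 and 9.5% for D10 to D15, so 6 of these 8 shares were above the nominal 5%. For limma-voom they were 4.22% for D15 against D5 and 7.1% across days. For DESeq2 they were 5.36% and, across days, 17.35% (34 of 196). The stage-only model had 4%. Unchanged genes with an unadjusted p under 0.05 were 3.71% to 4.93%. The limit first set on the false share in this check was exceeded, and it was replaced, after the shares were seen, by limits on the recovery of 4-fold changes and on the unadjusted share, with the same simulated data. With nothing changed between D6 and D7, 1 gene was called. A raised list was called (adjusted p = 4.1e-88 by camera, and 7.87e-10 with an estimated correlation), and 0 of 19 unchanged lists were. The simulated genes were given no correlation between members of a list. In the real data the estimated correlation for D15 against D5 ran from -0.106 (primitive blood) to 0.693 (sarcomere). The list check therefore cannot tell whether the preset correlation of camera was high enough for the real lists.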

Results

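Mouse embryonic stem cells differentiating toward heart muscle were harvested on 6 days, and their poly(A) RNA was sequenced. The cells were of the untreated TBX5-FTA line on the A2Lox.cre background, an embryonic stem cell background made for inserting transgenes. Cells of days 5, 6 and 7 (D5, D6, D7) carried the name cardiac progenitor cells and those of days 8, 10 and 15 (D8, D10, D15) the name immature cardiomyocytes. Each day had 3 libraries, 18 in all. Total counts per library ranged from 6689537 to 7122093 at D5, from 6208403 to 6406717 at D6 and from 6339689 to 6417737 at D7. They ranged from 5583288 to 6769054 at D8, from 5257601 to 6506504 at D10 and from 6121454 to 6831683 at D15. Of 23337 gene symbols, 13116 had enough counts to be tested. The series concerns gene networks that depend on Hedgehog signalling and its GLI transcription factors, and their part in the timing of differentiation. With no perturbed samples here, the comparisons ask how Hedgehog readouts, regulators of developmental timing, heart genes and markers of other cell types differed between harvests. Nothing in the labels states that the libraries of a day came from separate cultures, so the p-values measure the spread between libraries, which may be technical. The comparisons, the tests, 28 gene lists and the rule for naming genes were fixed before the data were examined. Levels are CPM, counts scaled to a common library size, as mean ± SD over 3 libraries, and log2 fold changes carry their SE. Counting intervals (95%) cover counting error only. Lower bounds set a group without a count at a floor of 3 counts over the group and take the count of the other group as exact. Where that other count is small, the true change may lie under the bound. Exons of Gli1, Hhip, Gli3, Foxf1a, Pou5f1, Myh6 and Myh7 overlap those of another annotated gene, and since the use of strand was not given, reads of that neighbour may be in their counts, which makes these values uncertain. The same holds for Lin28a, Col6a6, Ckm, Has2, Hand2 and other genes given with the methods.

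The 5 genes with the largest F over the 6 days were Bgn, Lin28a, Prtg, Nfib and Clca1. Bgn, which encodes the matrix proteoglycan biglycan, went from 13.4 ± 0.932 CPM at D5 through a low of 2.70 ± 0.776 at D7 to 1049 ± 43.3 at D15 (adjusted p = 3.69e-32 across days). Lin28a, an RNA-binding protein that blocks maturation of the let-7 microRNA, went from 1021 ± 39.7 CPM at D5 to 0.284 ± 0.0944 at D15 (adjusted p = 3.69e-32). Prtg, a surface receptor of early embryonic tissue, went from 1459 ± 28.2 to 1.02 ± 0.288 CPM (adjusted p = 1.66e-31), and the transcription factor gene Nfib from 2.58 ± 0.559 to 500.3 ± 20.1 CPM (adjusted p = 2.86e-31). Clca1, of a family of secreted regulators of chloride channels, had no count through D7 and reached 243.1 ± 11.1 CPM at D15 (adjusted p = 6.82e-26); its symbol was also used in the past for another gene. Across days, 11663 of the 13116 genes (88.9%) passed the test. Among the 6494 of them whose day means spanned at least 1 log2 unit, 2938 (45.2%) were highest at D15 and 1544 (23.8%) at D5. A further 602 were highest at D6, 307 at D7, 353 at D8 and 750 at D10. The mean distance between libraries, as the root mean square difference of log2 CPM, was 0.343 to 0.408 within a day. Between neighbouring harvests it was 0.695 from D5 to D6, 0.596 from D6 to D7, 0.607 from D7 to D8, 0.720 from D8 to D10 and 0.987 from D10 to D15.

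**Figure D1:**
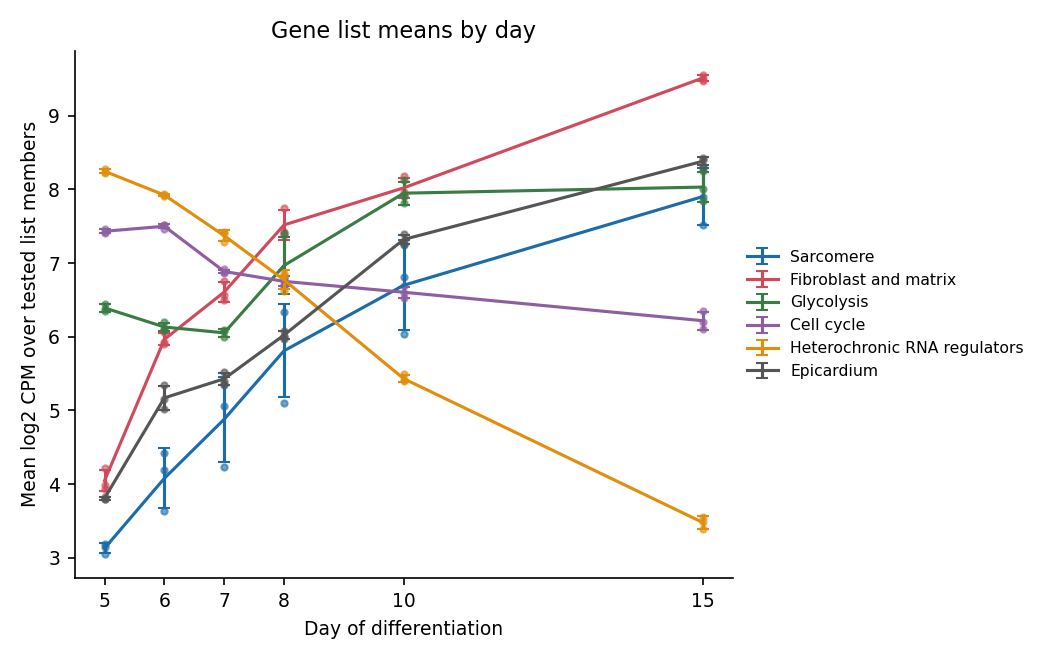
Mean log2 CPM of the tested members of 6 gene lists (vertical axis) by day of harvest (horizontal axis), with a point per library and the mean ± SD of 3 libraries. The sarcomere list went from 3.13 at D5 to 7.90 at D15 and the fibroblast and matrix list from 4.05 to 9.51, whereas the heterochronic list went from 8.25 to 3.48 and the cell cycle list from 7.43 to 6.22.

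Ptch1 and Hhip, transcripts that report Hedgehog signalling, were lower at the last harvest than at the first. Ptch1, the gene of the Hedgehog receptor and a direct target of GLI factors (mm10 chromosome 13, 63508328 to 63573598), went from 46.3 ± 8.72 CPM at D5 to 12.7 ± 5.53 at D15, a log2 fold change of -1.88 ± 0.27 (adjusted p = 7.65e-06). Hhip, a Hedgehog-binding antagonist induced by the pathway (chromosome 8, 79965851 to 80058006), had 51 counts at D5 and 0 at D15 and was at least 14-fold lower (adjusted p = 2.71e-07). Gli1, the GLI factor gene that the pathway switches on, was below the expression filter with 12 counts against 2, a ratio of 4.93 (interval 1.1 to 45.4). Summed over the 3 libraries of D5, D6, D7, D8, D10 and D15, counts were 12, 24, 9, 3, 3 and 2 for Gli1 and 7, 0, 0, 2, 0 and 0 for Mesp1, both under the filter. The 2 readouts tested both fell, also when adjusted over the list alone. The list did not pass the test against other genes (median -4.40, or -2.84 with Hhip at its bound; adjusted p = 0.19, and 0.528 with an estimated correlation).

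Genes that transmit the Hedgehog signal went both ways. Gli2, the main activating GLI factor (chromosome 1, 118834132 to 119053619), fell by 1.56 ± 0.09 log2 units (adjusted p = 6.13e-16), and Gli3, the main repressing one, fell by 0.98 ± 0.12 (adjusted p = 2.18e-07). The co-receptor genes Boc and Gas1 rose, by 1.82 ± 0.12 (adjusted p = 2.18e-14) and 2.69 ± 0.14 (adjusted p = 2.14e-11). Of 13 tested components 4 rose and 5 fell, both over all genes and adjusted over the list alone. The median was -0.04 although the mean was 0.17, and the test pointed down without passing (adjusted p = 0.934). Among forkhead and mesenchyme genes that act downstream of Hedgehog, Foxf1a (Foxf1; chromosome 8, 121084386 to 121088144) fell by 4.43 ± 0.29 (adjusted p = 3.08e-14) and Foxc1 by 2.09 ± 0.27. Osr1, a zinc finger gene of intermediate and lateral mesoderm, rose by 6.25 ± 0.23 and the ligand gene Wnt2b by 1.12 ± 0.14. Of the 6 tested, 2 rose and 4 fell, with equal counts adjusted over the list alone (median -1.44, adjusted p = 0.832).

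**Figure D2:**
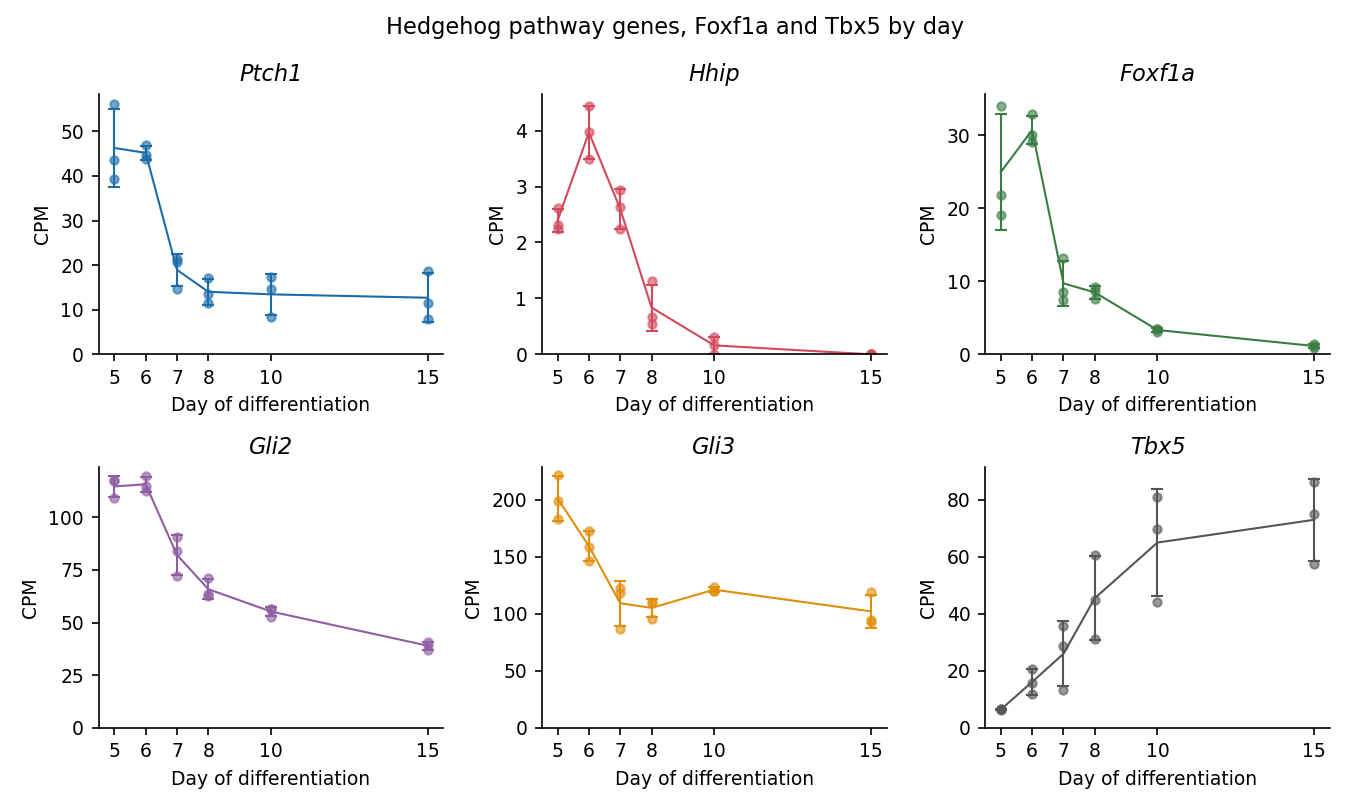
Level in CPM (vertical axes) of Ptch1, Hhip, Foxf1a, Gli2, Gli3 and Tbx5 by day of harvest (horizontal axis), with a point per library and the mean ± SD of 3 libraries. Ptch1 stood at 45.2 CPM at D6 and 18.9 at D7, and Tbx5 went from 6.42 CPM at D5 to 73.0 at D15.

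The heterochronic list, named after genes that set the order of developmental events, had 7 of 8 members lower at D15 and none higher, over all genes and adjusted over the list alone (median -4.54, adjusted p = 1.62e-04). That call was lost with an estimated correlation (adjusted p = 0.149). Lin28a (chromosome 4, 134003330 to 134018841) fell by 11.71 ± 0.16 log2 units (adjusted p = 3.40e-30) and its paralog Lin28b by 6.47 ± 0.17 (adjusted p = 6.86e-24). The chromatin protein gene Hmga2 and the RNA-binding protein gene Igf2bp1, both known targets of let-7, fell by 3.26 ± 0.07 (adjusted p = 4.17e-25) and 2.74 ± 0.07 (adjusted p = 9.93e-24). The exception was Igf2bp2, at 0.07 ± 0.07 (adjusted p = 0.34).

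Early progenitor genes were mostly lower, without a call for their lists. The homeobox gene Hoxb1 of the posterior second heart field fell by 5.79 ± 0.20 (adjusted p = 4.31e-20), and Isl1, a marker of that field, by 2.69 ± 0.43 (adjusted p = 1.44e-05). The ligand gene Wnt5a rose by 2.95 ± 0.09 (adjusted p = 1.09e-22). Aldh1a2, the enzyme gene of retinoic acid synthesis, whose symbol is also an older name of another gene, rose by 3.90 ± 0.16 (adjusted p = 5.23e-16). Of 15 tested members of the second heart field list, 5 rose and 10 fell (median -2.84, adjusted p = 0.427). Of 6 tested primitive streak and early mesoderm genes, 4 fell and only Pdgfra, a growth factor receptor of mesenchyme, rose, by 0.98 ± 0.07 (median -4.65, adjusted p = 0.415). Wnt3 and Eomes, both needed for the primitive streak, had no count at D15 and were at least 94-fold and at least 35.3-fold lower. Lhx1 had 80 counts against 3, a ratio of 21.9 (interval 7.24 to 109), and Mesp1, of the earliest heart mesoderm, 7 against 0, at least 1.92-fold lower. Pluripotency genes had 2 risen and 4 fallen of 6 (median -1.24, adjusted p = 0.584). Dnmt3b, a DNA methyltransferase gene, fell by 3.75 ± 0.14, and the transcription factor genes Tfcp2l1 and Klf2 rose by 2.76 ± 0.25 and 4.32 ± 0.42. Pou5f1, the gene of OCT4, had 57 counts at D5 and 1 at D15, a ratio of 46.9 (interval 8.08 to 1880; adjusted p = 5.01e-06). These counts were equal when adjusted over the list alone.

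Most heart muscle genes were higher at D15. The alpha myosin heavy chain gene Myh6 (chromosome 14, 54941921 to 54966927), of whose 50-base stretches 79.8% are unique, went from 7.77 ± 1.41 to 2156 ± 608 CPM (8.11 ± 0.83 log2 units, adjusted p = 9.57e-07). The fetal beta form Myh7 rose by 1.67 ± 0.46 (adjusted p = 0.0045) and the cardiac troponin T gene Tnnt2 by 2.90 ± 0.35 (adjusted p = 4.69e-06). Des, which encodes desmin filaments, rose by 3.20 ± 0.12 (adjusted p = 1.61e-16). Myoz2, of the Z disc, had no count at D5 and was at least 717-fold higher. Myom2, of the M band, had 647 counts against 2, a ratio of 394 (interval 109 to 3260). Of 25 sarcomere genes 23 rose, over all genes and adjusted over the list alone, and Tpm1 fell, by 0.56 ± 0.08 (median 4.79, adjusted p = 2.25e-04). That call was lost with an estimated correlation (adjusted p = 0.534). In the calcium handling and ion channel list 22 of 24 rose and the connexin genes Gja1 and Gjc1 fell, with equal counts adjusted over the list alone (median 4.74, adjusted p = 2.48e-04, and 0.528 with an estimated correlation). Cacna1g, a T-type calcium channel gene, rose by 5.32 ± 0.22 and the pacemaker channel gene Hcn4 by 3.30 ± 0.18. The atrial connexin gene Gja5 had no count at D5 and was at least 86-fold higher. Over the same span the fibroblast and matrix list rose by a median of 6.26, more than either muscle list.

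Cardiac transcription factor genes were divided. Tbx5 (chromosome 5, 119832668 to 119885219) rose by 3.50 ± 0.41 (adjusted p = 3.37e-06) and Nkx2-5 by 3.61 ± 0.75 (adjusted p = 4.28e-04). Mef2a, Mef2d and Gata6 rose by 2.25 ± 0.13, 1.20 ± 0.11 and 1.67 ± 0.12. Hand1, of the left ventricle and extraembryonic mesoderm, fell by 6.52 ± 0.24 (adjusted p = 3.49e-12), and Hand2 and Srf also fell. With 11 of 16 risen and 3 fallen, over all genes and adjusted over the list alone, the list did not pass (median 1.10, adjusted p = 0.19). Atrial markers rose in 8 of 9 cases, also adjusted over the list alone (median 3.99, adjusted p = 0.0073, and 0.443 with an estimated correlation). Among them, Sln, an inhibitor of the calcium pump in atrial muscle, had no count at D5 and was at least 241-fold higher. The lipid transfer gene Stard10 rose by 2.64 ± 0.16 and the transcription factor gene Nr2f2 by 3.99 ± 0.19. Ventricular markers went both ways, with 4 of 7 risen and 2 fallen by either adjustment (median 1.67, adjusted p = 0.972). The ventricular light chain gene Myl2 had 2001 counts against 3, a ratio of 811 (interval 277 to 3940), and Myl3 rose by 8.27 ± 1.14. Nppb, of the natriuretic peptide BNP, fell by 4.05 ± 0.58.

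Most energy metabolism genes were higher and most cell division genes lower at D15. Of 23 oxidative metabolism genes 22 rose and none fell, over all genes and adjusted over the list alone (median 3.12, adjusted p = 2.98e-06, and 0.446 with an estimated correlation). The fatty acid oxidation genes Acadvl, Acadl and Hadha rose by 3.12 ± 0.12 (adjusted p = 9.74e-20), 2.47 ± 0.10 and 1.69 ± 0.08, and Ckm, the muscle creatine kinase gene, was at least 816-fold higher. Glycolysis genes rose in 15 of 16 cases by either adjustment (median 1.86, adjusted p = 0.0011, and 0.528 with an estimated correlation). Aldoc, an aldolase gene, rose by 4.54 ± 0.25 (adjusted p = 2.50e-12) and Gpi1 by 1.72 ± 0.11. Pgk1, whose transcript shares 50-base stretches with other loci (46.1% unique), had a value of 1.19 ± 0.13. The exception was the glucose transporter gene Slc2a1, which fell from 3127 ± 153 to 529.4 ± 111 CPM (adjusted p = 3.24e-10). Of 30 cell cycle genes 29 fell and none rose, over all genes and adjusted over the list alone (median -1.24, adjusted p = 6.07e-11, and 0.193 with an estimated correlation). Rrm2, which supplies deoxynucleotides, fell by 1.88 ± 0.08 (adjusted p = 1.75e-18), the replication helicase genes Mcm5 and Mcm3 by 1.79 ± 0.08 and 1.43 ± 0.07, and the spindle checkpoint gene Bub1 by 1.57 ± 0.07. These changes came beside the median rise of 6.26 in fibroblast and matrix genes.

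Most fibroblast, epicardium and endothelium markers rose along with the muscle genes. All 14 fibroblast and matrix genes rose by either adjustment, over all genes and adjusted over the list alone (median 6.26, or 5.80 with genes at their bound; adjusted p = 9.49e-07, and 0.193 with an estimated correlation). The collagen genes Col3a1, Col6a1 and Col1a1 rose by 9.51 ± 0.23, 6.02 ± 0.15 and 6.51 ± 0.18, and Sparc, a collagen-binding matrix protein gene, by 2.95 ± 0.10. The list took 0.361% of counts at D5 and 5.56% at D15, against 0.348% and 1.09% for the sarcomere list. All 8 tested epicardium genes rose, also adjusted over the list alone (median 4.17, adjusted p = 5.24e-05), and this was the only list of the 28 whose call held with an estimated correlation (adjusted p = 0.0161). Wt1, the epicardial transcription factor gene, rose by 4.75 ± 0.09 (adjusted p = 7.07e-27), Upk3b by 3.34 ± 0.09 and Tbx18 by 6.92 ± 0.23. Endothelial genes rose in 12 of 13 cases by either adjustment (median 3.43, adjusted p = 0.013, and 0.528 with an estimated correlation). Among them, Eng rose by 3.17 ± 0.17 and Esam by 3.97 ± 0.30, whereas Etv2, which starts the endothelial and blood lineages, had 97 counts against 0, at least 26.6-fold lower.

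Smooth muscle genes were divided, with 3 of 8 risen and 4 fallen by either adjustment. Mylk, a myosin kinase gene, rose by 9.58 ± 0.18 (adjusted p = 5.83e-26) and Smtn by 1.88 ± 0.07, whereas Tagln fell by 1.91 ± 0.15 and Cald1 by 0.88 ± 0.12. The list's median was -0.44 and its mean 0.89, and the test pointed down without passing (adjusted p = 0.857). Fry pointed up for this list and passed (adjusted p = 0.0085). Of 5 tested primitive blood genes, Runx1 rose by 0.93 ± 0.27 and Tal1 fell by 3.75 ± 0.41. The list had a median of 0.29, a mean of -1.17 and a test that pointed down (adjusted p = 0.857). Of 4 tested endoderm genes, Sox17 and Afp rose and Cdh1 and Epcam fell, by 3.36 ± 0.41 and 3.91 ± 0.55. Their median was 0.01, their mean 0.60 and the test's direction down (adjusted p = 0.832). Neural markers had Ncam1 and Mtap2 (Map2) risen, by 3.49 ± 0.12 and 1.35 ± 0.21, and 4 of 6 fallen, among them Tubb3 and Nes (median -2.02, adjusted p = 0.832). Here too the test pointed down without passing, and fry pointed up and passed (adjusted p = 0.00327). Both tested skeletal muscle genes rose. Actn3, of fast fibres, rose by 3.03 ± 0.19, and Myh8, of perinatal muscle, had no count at D5 and was at least 691-fold higher (median 7.64, or 6.23 with Myh8 at its bound; adjusted p = 0.185). For all of these lists the counts adjusted over the list alone were equal.

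Signalling readouts differed by pathway. FGF readouts rose in 6 of 8 cases and fell in none, over all genes and adjusted over the list alone (median 1.30, adjusted p = 0.0371, and 0.443 with an estimated correlation). The feedback inhibitor genes Spry4 and Spry1 rose by 5.19 ± 0.27 and 1.98 ± 0.16, and Spred1 by 0.78 ± 0.09. BMP signalling genes fell in 6 of 12 cases and rose in 3 (median -0.90, adjusted p = 0.219). Msx2, a homeobox target of BMP, and the ligand genes Bmp2, Bmp5 and Bmp7 fell by 6.69 ± 0.27, 3.63 ± 0.19, 4.60 ± 0.22 and 1.98 ± 0.15. Canonical Wnt readouts fell in 5 of 9 cases and rose in 1 (median -0.99, adjusted p = 0.19). Tcf7, Lef1 and Dkk1 fell by 3.06 ± 0.15, 2.15 ± 0.17 and 5.35 ± 0.36, and Nkd1 rose by 1.86 ± 0.13. Notch readouts rose in 5 of 7 cases and fell in 1 (median 1.42, adjusted p = 0.43). Heyl was at least 85.6-fold higher, Dll4 rose by 4.25 ± 0.51 and Nrarp by 2.58 ± 0.45, and Hes1 fell by 1.09 ± 0.19. Stress and immediate early genes rose in 5 of 9 cases and fell in 1 (median 0.85, adjusted p = 0.52). Fos and Egr1 rose by 3.17 ± 0.30 and 3.14 ± 0.30, and Asns, the asparagine synthetase gene, fell by 2.10 ± 0.13. For these lists too the counts adjusted over the list alone were equal.

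The 10 largest rises from D5 to D15 under the naming rule all started from no count at D5. Col6a6, a collagen VI chain gene (chromosome 9, 105687809 to 105828160), was at least 5850-fold higher (adjusted p = 7.18e-14). Lower bounds were 1730-fold for Clca1, 1690-fold for the secreted protein gene Angptl7, 1650-fold for the mesothelial surface gene Msln and 1360-fold for Casq2, the calcium store protein of the cardiac sarcoplasmic reticulum. They were 1330-fold for the adhesion receptor gene Gpr133 (Adgrd1), 1020-fold for the purine enzyme gene Xdh, 839-fold for the secreted protein gene Igfbp7, 816-fold for Ckm and 792-fold for the fatty acid carrier gene Fabp4. Among the 10 largest falls, Lin28a and Prtg (chromosome 9, 72806874 to 72917291) were followed by Sall4, a stem cell zinc finger gene, with 2972 counts against 1, a ratio of 2440 (interval 438 to 96500). Prtg fell by 10.45 ± 0.15 (adjusted p = 5.34e-30). With no count at D15, Cbln1 was at least 179-fold lower, Vrtn at least 173-fold, Wnt3 at least 94-fold, Fam123c (Amer3) at least 87.9-fold and Sall3 at least 71.2-fold. Foxh1, a partner of Nodal signalling SMADs, fell by 9.34 ± 0.24 (adjusted p = 1.06e-23) and Trim71, a let-7 target, fell by 8.68 ± 0.30 (adjusted p = 1.66e-17). In total 5283 genes rose and 4948 fell, with changes of at least 2-fold in 3243 and 1946. The values of both days did not overlap for 10497 of the 13116 genes, where chance gives 10%. Of the 28 lists 11 passed.

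The second question was how the 3 cardiomyocyte days differed from the 3 progenitor days. The p-values of this contrast rest on the spread between libraries of a day and not on that between the days of a stage. An SD over 9 libraries holds both. Ratios and bounds of this contrast pool the counts of the 3 days of a stage, so the day with most counts weighs most. Log2 fold changes average the days instead. Among the 20 genes taken by the naming rule, Lox, which cross-links collagen, rose by 7.20 ± 0.11 log2 units (adjusted p = 1.19e-20) and Col6a3 by 7.37 ± 0.12 (adjusted p = 4.84e-19). Lin28a fell by 6.44 ± 0.07 (adjusted p = 6.51e-33), Prtg by 5.55 ± 0.07 (adjusted p = 5.87e-32), Foxh1 by 5.76 ± 0.13 and Sall4 by 5.54 ± 0.12. Msx1, a homeobox gene downstream of BMP, fell by 5.73 ± 0.31 (adjusted p = 5.82e-10) and the adhesion gene L1cam by 5.14 ± 0.29 (adjusted p = 2.77e-16). Clca1 had 5911 counts against 0, at least 2220-fold higher, and Vrtn 719 against 0 in the other direction, at least 212-fold lower. Ndufa4l2, a mitochondrial protein gene induced by low oxygen, had 2103 counts against 1, a ratio of 2370 (interval 425 to 93800). Ptprq had 1697 against 2, a ratio of 957 (interval 265 to 7910). For S100a4, a calcium-binding protein gene of fibroblasts with 52.6% unique stretches, 733 against 3 gave a ratio of 276 (interval 94 to 1340). Averaged over days, the fitted changes were smaller, 328-fold for Ndufa4l2, 184-fold for Ptprq and 125-fold for S100a4. Each of these genes had a day without a count, so the fitted values depend on the prior count. Over 9 libraries each, Angptl7 stood at 0.458 ± 0.873 CPM in progenitor and 163.2 ± 94.8 in cardiomyocyte days (adjusted p = 2.02e-09), Col6a6 at 0.554 ± 0.991 and 288 ± 400 (adjusted p = 1.99e-11), and the growth factor gene Fgf1 at 0.153 ± 0.186 and 28.5 ± 18 (adjusted p = 9.49e-22). The transcription factor gene Hlf rose by 6.90 ± 0.23. Cbln1 stood at 21.7 ± 13.3 and 0.373 ± 0.303 CPM, Fam123c at 9.18 ± 5.11 and 0.220 ± 0.439, and Wnt3 at 7.34 ± 6.81 and 0.296 ± 0.423.

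Between the stages the Hedgehog and heart genes kept the directions seen from D5 to D15. Ptch1 fell by 1.34 ± 0.16 (adjusted p = 8.44e-07), from 36.8 ± 14.2 to 13.4 ± 3.93 CPM over 9 libraries each, and Hhip went from 2.99 ± 0.804 to 0.332 ± 0.443 CPM (adjusted p = 1.64e-10). Gli2 fell by 0.98 ± 0.05, Gli3 by 0.48 ± 0.07 and Foxf1a by 2.61 ± 0.15 (adjusted p = 1.32e-15). Myh6 rose by 4.99 ± 0.41, Myh7 by 0.91 ± 0.26, Tnnt2 by 1.41 ± 0.19, Tbx5 by 2.11 ± 0.22 and Nkx2-5 by 2.43 ± 0.44. Isl1 fell by 0.87 ± 0.23 (adjusted p = 0.0023), a call lost when the stages were the only groups of the model (adjusted p = 0.0906, with 1.68e-04 to 0.0906 over the alternatives). Pou5f1 did not pass (0.909 ± 1.34 against 0.0953 ± 0.128 CPM, adjusted p = 0.777) but did in that stage-only model (adjusted p = 0.0226, the lowest over the alternatives, whose highest was 1). Mesp1 had 7 counts against 2, a ratio of 3.1 (interval 0.591 to 30.6), a difference not detectable at this depth.

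Lists called between the stages were 11. All 8 heterochronic genes fell (median -2.32, adjusted p = 2.88e-05, and 0.0851 with an estimated correlation), among them Lin28b by 3.20 ± 0.08 and Hmga2 by 1.29 ± 0.04. All 30 cell cycle genes fell (median -0.74, adjusted p = 1.13e-11, and 0.184 with an estimated correlation), Mcm5 by 1.09 ± 0.05 and Bub1 by 1.00 ± 0.04. Sarcomere genes rose in 23 of 25 cases (median 2.71, adjusted p = 2.88e-05, and 0.478), calcium handling and ion channel genes in 22 of 24 with 2 falls (median 2.54, adjusted p = 1.29e-04, and 0.478) and atrial markers in 8 of 9 (median 2.11, adjusted p = 0.0033, and 0.318), the last value of each being the adjusted p with an estimated correlation. Oxidative metabolism genes rose in 22 of 23 cases (median 1.36, adjusted p = 1.24e-05, and 0.393 with an estimated correlation), Acadvl by 1.68 ± 0.07 and the lipase gene Lpl by 4.39 ± 0.10. Glycolysis genes rose in 15 of 16 cases with Slc2a1 the fall (median 1.42, adjusted p = 3.57e-05, and 0.393 with an estimated correlation). Of fibroblast and matrix genes 11 of 14 rose (median 3.27, adjusted p = 2.19e-06, and 0.206 with an estimated correlation). With genes at their bound, which pools counts over days and can exceed the fitted value, the median was 3.76. Epicardium genes rose in 8 of 8 cases (median 2.60, adjusted p = 6.94e-05) and kept the call with an estimated correlation (adjusted p = 0.0224). BMP signalling genes fell in 8 of 12 cases and rose in 1 (median -0.58, adjusted p = 0.0107, and 0.318 with an estimated correlation). FGF readouts rose in 7 of 8 cases (median 0.89, adjusted p = 0.0146, and 0.318 with an estimated correlation). For these 11 lists the counts adjusted over the list alone were equal. In total 5156 genes rose and 4955 fell, with changes of at least 2-fold in 2179 and 744. Values did not overlap for 16.9% of genes, and for at most 2.1% in the 9 other splits of the 6 days into 3 and 3. Only the real split parts early from late days, so a gradual trend would also rank it highest. Its rank cannot show a boundary between D7 and D8.

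From D5 to D6 mesenchymal and epicardial genes rose while FGF and Wnt readouts fell. Fibroblast and matrix genes rose in 11 of 14 cases, Col3a1 by 4.43 ± 0.20 (adjusted p = 1.74e-09) and Postn, a matrix gene of valves and fibroblasts, by 4.73 ± 0.43 (list median 1.09, adjusted p = 6.57e-07, and 0.164 with an estimated correlation). Epicardium genes rose in 5 of 8 cases, Wt1 by 1.68 ± 0.10 (adjusted p = 3.60e-13) and Bnc1 by 1.72 ± 0.10, and Lrrn4 fell (median 1.70, adjusted p = 0.0023, and 0.071 with an estimated correlation). FGF readouts fell in 7 of 8 cases, Spred1 by 1.03 ± 0.10 and Il17rd by 1.04 ± 0.15 (median -1.14, adjusted p = 1.95e-04, and 0.118 with an estimated correlation). Canonical Wnt readouts fell in 5 of 9 cases and rose in 1, with Lef1 down by 1.24 ± 0.16 and Dkk1 by 1.96 ± 0.24 (median -0.62, adjusted p = 0.0156, and 0.164 with an estimated correlation). Heterochronic genes fell in 5 of 8 cases, Lin28a by 0.96 ± 0.07 (adjusted p = 7.56e-12), with a list median of -0.39 (adjusted p = 0.0156, and 0.289 with an estimated correlation). Counts adjusted over the list alone were equal for these 5 lists.

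The other 6 lists called from D5 to D6 lost their call when single libraries were left out. The fibroblast and matrix median was 1.09 over this step. Smooth muscle genes fell in 5 of 8 cases and rose in 1 (median -0.46, adjusted p = 0.0342, and 0.369 with an estimated correlation), Tagln by 1.74 ± 0.15, while Mylk rose by 3.04 ± 0.35; without 1 of the D6 libraries the adjusted p was 0.0514. Stress and immediate early genes fell in 5 of 9 cases, Asns by 0.99 ± 0.12 (median -0.99, adjusted p = 0.0342, and 0.412 with an estimated correlation), with 0.016 to 0.0589 when libraries were left out in turn (lost without 1 D5 and without each of 2 D6 libraries). Endothelial genes rose in 8 of 13 cases, Tek by 2.45 ± 0.17 and Tie1 by 3.88 ± 0.49, and Flt1 and Etv2 fell (median 1.56, adjusted p = 0.0498, and 0.481 with an estimated correlation), with 0.0274 to 0.0601 when libraries were left out (lost without any of the 3 D5 libraries). For those 3 lists the counts adjusted over the list alone were equal. Hedgehog components rose in 5 of 13 cases and fell in 1, or 6 and 1 adjusted over the list alone (median 0.34, adjusted p = 0.0498, and 0.412 with an estimated correlation), with 0.043 to 0.0748 when libraries were left out (lost for 5 of 6), and 0.0503 with RLE factors. Hhat, which attaches palmitate to the ligand, rose by 1.23 ± 0.24, and the transducer gene Smo by 0.30 ± 0.07. Cardiac transcription factor genes rose in 7 of 16 cases and fell in 2, or 8 and 2 adjusted over the list alone (median 0.52, adjusted p = 0.0498, and 0.529 with an estimated correlation), with 0.0151 to 0.0853 when libraries were left out (lost for 5 of 6). Gata4 and Hand2 rose by 1.26 ± 0.15 and 0.64 ± 0.09, and Srf fell by 0.63 ± 0.08. Atrial markers rose in 4 of 9 cases and fell in 1, or 5 and 1 adjusted over the list alone (median 1.29, adjusted p = 0.0498, and 0.417 with an estimated correlation), with 0.0172 to 0.0551 when libraries were left out (lost for 4 of 6). Nr2f2 and the potassium channel gene Kcna5 rose by 3.09 ± 0.20 and 1.67 ± 0.18.

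Among single genes from D5 to D6, Nlrp4a had 141 counts against 1, a ratio of 155 (interval 27.4 to 6180), and the endothelial receptor gene Cd93 134 against 2, a ratio of 73.9 (interval 20.1 to 616). Islr, a marker of mesenchymal stromal cells, and Enpp1 had no count at D5 and were at least 14.7-fold and at least 9.92-fold higher. Aldh1a2 fell by 3.74 ± 0.33, the cytokine receptor gene Tnfrsf12a by 3.23 ± 0.25 (adjusted p = 3.13e-11) and Vrtn by 3.09 ± 0.25, and the exchanger gene Slc24a4 had 14 counts at D5 against 1, a ratio of 12.7 (interval 1.93 to 537). Pou5f1 went from 57 counts to 0, at least 17.2-fold lower (adjusted p = 6.30e-06), and Mesp1 from 7 to 0, at least 2.12-fold lower. Gli3 fell by 0.34 ± 0.11 (adjusted p = 0.0239), Tbx5 rose by 1.33 ± 0.47 (adjusted p = 0.0451) and Tnnt2 by 1.15 ± 0.34 (adjusted p = 0.0191), each lost when single libraries were left out. Over those fits the adjusted p was 0.0183 to 0.11 for Gli3 (lost without 2 of the D5 and 2 of the D6 libraries), 0.043 to 0.154 for Tbx5 (lost without any D5 and 2 of the D6 libraries) and 0.0211 to 0.0655 for Tnnt2 (lost without 2 of the D5 libraries and 1 D6 library). For Ptch1 the value was -0.04 ± 0.23 (adjusted p = 0.93), for Hhip 0.73 ± 0.35 (adjusted p = 0.111), for Gli2 0.01 ± 0.08, for Foxf1a 0.30 ± 0.18, for Isl1 -0.64 ± 0.34, for Nkx2-5 0.34 ± 1.05, for Myh6 2.10 ± 0.92 and for Myh7 0.43 ± 0.48, none of which passed. Gli1 counts were 24 at D6 against 12 at D5, a ratio of 2.2 (interval 1.06 to 4.84). In all, 2386 genes rose and 2154 fell, 649 and 510 by at least 2-fold, and values did not overlap for 48.8% of genes (10% by chance).

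From D6 to D7 all 30 cell cycle genes fell, and so did the Hedgehog readout Ptch1. Ptch1 fell by 1.26 ± 0.25 (adjusted p = 0.0012), from 45.2 ± 1.56 to 18.9 ± 3.64 CPM, Gli2 by 0.50 ± 0.08 (adjusted p = 2.09e-05), Gli3 by 0.55 ± 0.12 (adjusted p = 0.0013) and Foxf1a by 1.66 ± 0.20 (adjusted p = 2.07e-07), from 30.7 ± 1.96 to 9.73 ± 3.10 CPM. Gli1 had 24 counts at D6 against 9 at D7, a ratio of 2.7 (interval 1.21 to 6.61). Hhip did not pass, at -0.61 ± 0.35 (adjusted p = 0.201), nor did the readout list, with 1 of 2 lower, also adjusted over the list alone (adjusted p = 0.105, and 0.365 with an estimated correlation). Of 30 cell cycle genes all fell, over all genes and adjusted over the list alone, Rrm2 by 0.87 ± 0.08 (adjusted p = 1.26e-09), Mcm5 by 0.81 ± 0.08 and Aurka by 0.71 ± 0.07. That list had a median of -0.57 (adjusted p = 3.04e-24) and held with an estimated correlation (adjusted p = 0.0418). The fibroblast and matrix list rose over the same step, by a median of 0.64. Primitive streak genes also kept their call there (adjusted p = 0.0418). Of 6 tested, 3 fell, or 4 adjusted over the list alone (median -1.29, adjusted p = 0.0021), Pdgfra by 0.76 ± 0.07, while the retinoic acid-degrading enzyme gene Cyp26a1 had 51 counts against 1, a ratio of 51.7 (interval 8.87 to 2080), and Lhx1 9 against 0, at least 3.04-fold lower.

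Heterochronic genes fell in 6 of 8 cases from D6 to D7 by either adjustment, over all genes and adjusted over the list alone, Lin28a by 1.43 ± 0.07 (adjusted p = 1.07e-14) and Hmga2 by 1.05 ± 0.07 (median -0.47, adjusted p = 4.30e-05, and 0.0513 with an estimated correlation). BMP signalling genes fell in 6 of 12 cases and rose in 2 by either adjustment (median -0.44, adjusted p = 0.0163, and 0.33 with an estimated correlation), Bmp4 by 0.78 ± 0.12 and Msx1 by 1.86 ± 0.29. Stress and immediate early genes rose in 4 of 9 cases by either adjustment (median 0.78, adjusted p = 0.014, and 0.33 with an estimated correlation), Asns by 1.11 ± 0.12 and Trib3, a stress-induced pseudokinase gene, by 1.83 ± 0.31. Fibroblast and matrix genes rose in 6 of 14 cases, or 7 adjusted over the list alone (median 0.64, adjusted p = 1.21e-04, and 0.33 with an estimated correlation), Col1a1 by 1.58 ± 0.14 and Sparc by 0.69 ± 0.10. Sarcomere genes rose in 4 of 25 cases, or 2 adjusted over the list alone (median 1.05, adjusted p = 0.0155, and 0.841 with an estimated correlation), Des by 1.41 ± 0.11 and the atrial light chain gene Myl4 by 1.79 ± 0.44. That call was lost without 1 D6 library (adjusted p = 0.0743) and without 1 D7 library (adjusted p = 0.0952), against 2.71e-04 at the lowest.

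Single genes that rose from D6 to D7 were Fam129a, by 4.22 ± 0.63 (adjusted p = 1.29e-05), Gsta3, a glutathione transferase gene with 36 counts against 0 (at least 11.8-fold), Slc24a4, with 24 against 1 (ratio 23.7, interval 3.86 to 973), and the activin subunit gene Inhbb, with 9 against 0 (at least 2.96-fold, adjusted p = 0.0188). The Inhbb call was lost in limma-voom (adjusted p = 0.107) and without any 1 of 2 D6 libraries or 1 D7 library (0.0109 to 0.107 over the alternatives). The arrestin-related genes Txnip and Arrdc4, which limit glucose uptake, fell by 2.83 ± 0.21 (adjusted p = 2.41e-07) and 2.92 ± 0.29. The asparaginase gene Aspg had 52 counts against 3, a ratio of 17.6 (interval 5.69 to 88), and Rubie, a noncoding gene with 37.6% unique stretches, a value of -2.82 ± 0.35. The heart genes of the fixed set did not pass in this step, with Tbx5 at 0.69 ± 0.39, Nkx2-5 at 0.60 ± 0.94, Isl1 at -0.57 ± 0.37, Myh6 at 1.70 ± 0.68 (adjusted p = 0.0796), Myh7 at 0.20 ± 0.46 and Tnnt2 at 0.14 ± 0.33. In all, 1977 genes rose and 2007 fell, 410 and 275 by at least 2-fold, without overlap for 42.5% of genes (10% by chance). Of the 28 lists 7 passed.

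At the passage from progenitor to cardiomyocyte days, D7 to D8, glycolysis and matrix genes rose. Glycolysis genes rose in 12 of 16 cases, or 13 adjusted over the list alone, and Slc2a1 fell (median 0.90, adjusted p = 4.00e-07, and 0.393 with an estimated correlation). One D8 library stood above the others, with a mean log2 CPM of 7.411 for the list against 6.786 and 6.704, where D7 had 6.05 ± 0.05. Without it 8 genes rose over all genes and the median was 0.621 (camera p = 1.06e-08 before adjustment, and 0.0569 with an estimated correlation). Tpi1 rose by 1.38 ± 0.17 (adjusted p = 6.34e-05), the lactate exporter gene Slc16a3 by 2.45 ± 0.31 and the phosphofructokinase gene Pfkl by 2.55 ± 0.34. Fibroblast and matrix genes rose in 8 of 14 cases, or 9 adjusted over the list alone (median 0.93, adjusted p = 1.61e-08, and 0.129 with an estimated correlation), Col1a1 by 1.87 ± 0.14 and Col3a1 by 2.21 ± 0.16. Epicardium genes rose in 4 of 8 cases by either adjustment (median 0.29, adjusted p = 0.0017, and 0.0702 with an estimated correlation), Wt1 by 0.94 ± 0.07 (adjusted p = 8.39e-11) and Tcf21 by 2.28 ± 0.25. Heterochronic genes fell in 5 of 8 cases and Hmga2 rose, by 0.27 ± 0.07, by either adjustment (median -0.47, adjusted p = 3.07e-04, and 0.129 with an estimated correlation). Lin28a fell by 1.48 ± 0.08 and Nr6a1, a nuclear receptor gene of early embryos, by 1.44 ± 0.12. BMP signalling genes fell in 7 of 12 cases and Bambi rose, by either adjustment (median -0.46, adjusted p = 0.0042, and 0.291 with an estimated correlation), Msx1 by 2.04 ± 0.41 and Id3 by 0.80 ± 0.17. Cell cycle genes fell in 9 of 30 cases, or 10 adjusted over the list alone (median -0.15, adjusted p = 0.0035, and 0.535 with an estimated correlation), Foxm1, a regulator of mitotic genes, by 0.49 ± 0.09.

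Sarcomere genes rose in 6 of 25 cases from D7 to D8 and Cryab fell, by either adjustment, over all genes and adjusted over the list alone (median 1.04, adjusted p = 0.0042, and 0.607 with an estimated correlation), Des by 0.81 ± 0.10 and Myl2 by 2.42 ± 0.62. That call was lost without 1 D7 library (adjusted p = 0.0771) and without 1 D8 library (0.052), the lowest over the alternatives being 1.37e-05. Oxidative metabolism genes rose in 6 of 23 cases and Slc2a4 fell, by either adjustment (median 0.29, adjusted p = 0.0279, and 0.607 with an estimated correlation), Lpl by 2.12 ± 0.15, beside a fibroblast and matrix median of 0.93, and that call was lost without 1 D7 library (0.112) or 1 D8 library (0.124), the lowest being 0.0042. Myh6 rose by 2.05 ± 0.60 (adjusted p = 0.0253), a call lost in a fit of both days alone (adjusted p = 0.147) and without 2 of the D7 and 2 of the D8 libraries (0.0107 to 0.0991). Hhip fell by 1.57 ± 0.45 (adjusted p = 0.0105; 0.0505 without 1 D8 library, the highest over the alternatives, and 0.0058 at the lowest) and Gli2 by 0.32 ± 0.08 (adjusted p = 0.0051; 0.0537 without 1 D7 library, the highest, and 6.12e-04 at the lowest). Other fixed genes did not pass, with Ptch1 at -0.42 ± 0.28, Gli3 at -0.06 ± 0.12, Foxf1a at -0.19 ± 0.23, Tbx5 at 0.82 ± 0.35, Nkx2-5 at 1.34 ± 0.75, Isl1 at 0.43 ± 0.38, Myh7 at 0.14 ± 0.45 and Tnnt2 at 0.30 ± 0.33. Gli1 had 9 counts against 3, a ratio of 2.82 (interval 0.704 to 16.2), not detectable as a difference at this depth.

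Clca1 and the calmodulin-binding gene Nrgn had no count at D7 and were at least 33.7-fold and at least 20.6-fold higher at D8, and Angptl7 and Hlf rose by 4.99 ± 0.45 and 4.83 ± 0.51. The amino acid transporter gene Slc7a3 fell by 4.21 ± 0.20 (adjusted p = 1.40e-15), Trib3 by 3.09 ± 0.37 and the connexin gene Gjb5 by 2.86 ± 0.43, and Vrtn had 21 counts against 0, at least 6.58-fold lower. In all, 1648 genes rose and 1520 fell between D7 and D8, 576 and 133 by at least 2-fold, without overlap for 37.4% of genes (10% by chance). Of the 28 lists 8 passed.

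**Figure D3:**
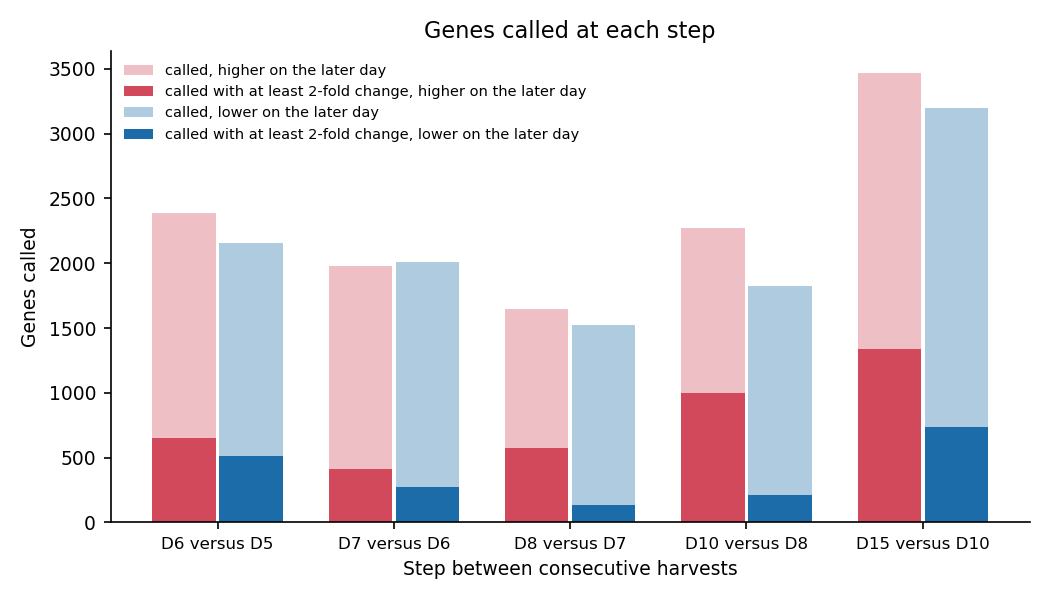
Number of genes called higher or lower (vertical axis) at each step between neighbouring harvests (horizontal axis), as light bars for all calls at an adjusted p under 0.05 and dark bars for calls of at least 2-fold. The bars run from 1648 higher and 1520 lower between D7 and D8 to 3467 higher and 3195 lower between D10 and D15.

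From D8 to D10 timing regulators fell steeply and epicardial genes rose, and both list calls held with an estimated correlation. Heterochronic genes fell in 7 of 8 cases, over all genes and adjusted over the list alone, Lin28a by 3.22 ± 0.11 (adjusted p = 6.87e-19), Trim71 by 2.62 ± 0.23 and Nr6a1 by 2.32 ± 0.17 (median -0.95, adjusted p = 1.85e-08, and 0.0132 with an estimated correlation). Epicardium genes rose in 6 of 8 cases by either adjustment, Wt1 by 0.94 ± 0.07 and Upk3b by 1.14 ± 0.08, and Msln had 200 counts against 1, a ratio of 211 (interval 37.5 to 8390; median 0.88, adjusted p = 2.15e-06, and 0.0048 with an estimated correlation). Smooth muscle genes rose in 4 of 8 cases by either adjustment, Mylk by 3.08 ± 0.14 (adjusted p = 1.67e-15) and Myh11 by 3.04 ± 0.32 (median 0.51, adjusted p = 2.95e-04, and 0.0987 with an estimated correlation). FGF readouts rose in 6 of 8 cases, or 7 adjusted over the list alone, Spry4 by 2.65 ± 0.31 (median 1.14, or 1.09 with a gene at its bound; adjusted p = 1.92e-04, and 0.0987 with an estimated correlation). Fibroblast and matrix genes rose in 7 of 14 cases and Postn fell, or 7 and 2 adjusted over the list alone, Col6a1 by 1.78 ± 0.12 and the proteoglycan gene Dcn by 2.35 ± 0.17 (median 0.52, adjusted p = 0.0044, and 0.463 with an estimated correlation). Neural genes rose in 3 of 6 cases by either adjustment, Ncam1 by 1.95 ± 0.11 and Nes by 1.05 ± 0.13 (median 0.63, adjusted p = 0.0228, and 0.113 with an estimated correlation), lost without 1 D8 library (0.0728) or 1 D10 library (0.0669), the lowest over the alternatives being 0.0247. Of the skeletal muscle genes, Actn3 rose by 1.29 ± 0.15, and Myh8 had 27 counts against 0, at least 9.52-fold higher, which passed when adjusted over the list alone (median 3.79, or 2.27 with Myh8 at its bound, adjusted p = 0.0346, and 0.159 with an estimated correlation). That list call rests on these 2 tested genes. Myod1, Myf5, Myf6 and Pax7 had no count at D8 or D10, Myog had 0 and 2 and Myh3 had 1 and 0.

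Muscle and metabolic lists rose from D8 to D10 beside the fibroblast and matrix median of 0.52. Calcium handling and ion channel genes rose in 14 of 24 cases, or 15 adjusted over the list alone, Cacna1g by 3.83 ± 0.30 (adjusted p = 5.43e-11; list median 0.88, adjusted p = 3.95e-05, and 0.463 with an estimated correlation). Sarcomere genes rose in 7 of 25 cases by either adjustment, Csrp3 by 2.06 ± 0.44 and Tpm1 by 0.48 ± 0.08 (median 0.71, adjusted p = 2.85e-04, and 0.548 with an estimated correlation). Oxidative metabolism genes rose in 11 of 23 cases, or 13 adjusted over the list alone, Acadvl by 0.89 ± 0.11 and the nuclear receptor gene Esrra by 0.83 ± 0.15 (median 0.83, adjusted p = 1.92e-04, and 0.463 with an estimated correlation). Glycolysis genes rose in 14 of 16 cases by either adjustment, Gpi1 by 0.91 ± 0.11 and Tpi1 by 1.21 ± 0.17 (median 0.92, adjusted p = 3.80e-09, and 0.199 with an estimated correlation). Cell cycle genes fell in 10 of 30 cases and Ccne1 rose, or 16 and 1 adjusted over the list alone, Ube2c by 0.57 ± 0.09 (median -0.17, adjusted p = 0.0012, and 0.463 with an estimated correlation). Foxf1a fell by 1.35 ± 0.28 (adjusted p = 3.19e-04) and Gli2 by 0.25 ± 0.09 (adjusted p = 0.0254), the latter lost without 1 D8 library (0.141) or 1 D10 library (0.105), with 0.02 at the lowest over the alternatives. Hhip had 16 counts against 3, a ratio of 5.04 (interval 1.44 to 27; adjusted p = 0.0282), lost in DESeq2 (0.0655) and without 1 D8 or 2 of the D10 libraries, with 0.0191 to 0.155 over the alternatives. Ptch1 at -0.05 ± 0.30, Gli3 at 0.21 ± 0.12, Tbx5 at 0.51 ± 0.33, Nkx2-5 at 0.40 ± 0.64, Isl1 at -0.20 ± 0.38, Myh6 at 1.07 ± 0.56, Myh7 at 0.59 ± 0.44 and Tnnt2 at 0.58 ± 0.32 did not pass.

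Single genes that rose from D8 to D10 included Hic1, a transcriptional repressor gene, with 241 counts against 2 (ratio 127, interval 34.9 to 1060), and Fam110c and the matrix gene Aspn, at least 10.9-fold and at least 9.52-fold higher. The adhesion gene L1cam had 45 counts at D8 against 3, a ratio of 14.2 (interval 4.55 to 71.4), Sall3 26 against 1, a ratio of 24.6 (interval 4.04 to 1010), and Fam123c 12 against 0, at least 3.78-fold lower (adjusted p = 0.0077; 0.0643 without 1 D8 library, the highest over the alternatives, and 0.0039 at the lowest). Wnt3 had 15 against 1, a ratio of 14.2 (interval 2.18 to 597; adjusted p = 0.0206), lost without 1 D8 or 2 of the D10 libraries (0.0134 to 0.0907 over the alternatives). In all, 2272 genes rose and 1821 fell, 999 and 213 by at least 2-fold, without overlap for 42.6% of genes (10% by chance). Of the 28 lists 12 passed.

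From D10 to D15, the longest gap, oxidative metabolism genes rose and cell cycle genes fell further, while the fibroblast and matrix median was 0.95. Oxidative metabolism genes rose in 19 of 23 cases, or 20 adjusted over the list alone, Ckm by 7.92 ± 0.27 (adjusted p = 5.26e-18), Acadl by 1.25 ± 0.10 and the fatty acid transporter gene Cd36 by 2.22 ± 0.16 (median 1.15, adjusted p = 5.56e-07, and 0.388 with an estimated correlation). Cell cycle genes fell in 27 of 30 cases by either adjustment, over all genes and adjusted over the list alone, Mcm5 by 0.74 ± 0.08 (adjusted p = 8.80e-09) and Rrm2 by 0.66 ± 0.08 (median -0.36, adjusted p = 5.15e-06, and 0.388 with an estimated correlation). Heterochronic genes fell in 7 of 8 cases and Igf2bp2 rose, by 0.34 ± 0.07, by either adjustment; Hmga2 fell by 1.98 ± 0.08 (adjusted p = 5.33e-19) and Lin28b by 3.63 ± 0.22 (median -1.72, adjusted p = 2.03e-04, and 0.147 with an estimated correlation). Sarcomere genes rose in 9 of 25 cases and Tnni1 and Des fell, by either adjustment, Myom2 by 4.93 ± 0.32 and Myoz2 by 5.78 ± 0.29 (median 0.93, adjusted p = 0.0028, and 0.764 with an estimated correlation). Calcium handling and ion channel genes rose in 12 of 24 cases and fell in 2 by either adjustment, Cacna1g by 2.50 ± 0.17 and Casq2 by 4.34 ± 0.27 (median 0.94, adjusted p = 0.0068, and 0.764 with an estimated correlation), lost without 1 D10 library (0.0529, against 3.92e-04 at the lowest).

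Most markers of fibroblasts, endothelium and epicardium and most FGF and stress genes also rose from D10 to D15. Fibroblast and matrix genes rose in 10 of 14 cases and Postn fell, by 1.43 ± 0.33, by either adjustment, over all genes and adjusted over the list alone (median 0.95, adjusted p = 4.31e-05, and 0.388 with an estimated correlation), Dcn by 2.44 ± 0.16. Endothelial genes rose in 9 of 13 cases and fell in 1 by either adjustment, Flt1, a VEGF receptor gene, by 2.77 ± 0.25 and Cldn5 by 2.23 ± 0.32 (median 1.80, adjusted p = 0.0082, and 0.589 with an estimated correlation). Epicardium genes rose in 5 of 8 cases and Tbx18 fell, by 0.93 ± 0.12, by either adjustment, Msln by 4.34 ± 0.15 and Lrrn4 by 1.65 ± 0.08 (median 0.74, adjusted p = 0.0041, and 0.147 with an estimated correlation). FGF readouts rose in 6 of 8 cases, or 7 adjusted over the list alone, Spry4 by 2.17 ± 0.20 (median 1.04, adjusted p = 0.0028, and 0.32 with an estimated correlation). Stress and immediate early genes rose in 7 of 9 cases by either adjustment, Trib3 by 3.89 ± 0.38, Asns by 1.56 ± 0.16 and Fos by 2.46 ± 0.28 (median 1.56, adjusted p = 0.0082, and 0.388 with an estimated correlation). Foxf1a fell by 1.53 ± 0.41 (adjusted p = 0.0023), Gli2 by 0.50 ± 0.09 (adjusted p = 3.73e-05) and Isl1 by 1.71 ± 0.47 (adjusted p = 0.0052). Ptch1 at -0.12 ± 0.30, Gli3 at -0.24 ± 0.12, Tbx5 at 0.16 ± 0.32, Nkx2-5 at 0.93 ± 0.58, Myh6 at 1.20 ± 0.55, Myh7 at 0.31 ± 0.43 and Tnnt2 at 0.73 ± 0.32 did not pass, and Hhip, Gli1, Mesp1 and Pou5f1 were at or under the floor of 3 counts on both days.

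The acute phase gene Saa3 had no count at D10 and was at least 262-fold higher at D15, and Xdh and Fabp4 rose by 8.87 ± 0.29 (adjusted p = 2.03e-16) and 7.87 ± 0.31. Has2, the hyaluronan synthase gene of the early heart, fell by 6.39 ± 0.29 (adjusted p = 8.11e-15), from 40.0 ± 7.56 to 0.443 ± 0.407 CPM. The steroid dehydrogenase gene Hsd3b6 had 386 counts at D10 against 1, a ratio of 388 (interval 69.2 to 15400), Tcerg1l 126 against 1, a ratio of 127 (interval 22.3 to 5040), and Nlrp4a 96 against 0, at least 32.1-fold lower. In all, 3467 genes rose and 3195 fell between D10 and D15, 1338 and 738 by at least 2-fold, without overlap for 56.6% of genes (10% by chance). The balance depended on scaling, since with upper quartile factors 44.3% of 6873 calls were higher. Of the 28 lists 10 passed. Over all comparisons 6 list calls held with an estimated correlation, and 64 did not. Those that held were epicardium from D5 to D15, between the stages and from D8 to D10, cell cycle and primitive streak from D6 to D7, and heterochronic genes from D8 to D10.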

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

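No call of a named gene or list reversed its direction under any alternative. The replicate block was not run. No paired analysis was possible because the columns carry no replicate number to match a library of one day to a library of another, although the sample titles do. Pairing by column order was left out by choice, though sarcomere deviations fell in that order on all 6 days. Such a block would bear on calls of heart genes. Steps of heart genes that did not pass, those of Myh6 among them, were therefore tested against the whole spread between libraries of a day, and not passing does not show that they did not change.

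Requiring at least 2-fold left 5189 genes for D15 against D5 (3243 higher, 1946 lower), 2923 between the stages (2179 and 744), 1159 from D5 to D6 (649 and 510), 685 from D6 to D7 (410 and 275), 709 from D7 to D8 (576 and 133), 1212 from D8 to D10 (999 and 213) and 2076 from D10 to D15 (1338 and 738). That follows from the threshold. A range of at least 2 log2 units in place of 1 left 3153 genes for the peak day, with 496 at D5, 152 at D6, 100 at D7, 172 at D8, 401 at D10 and 1832 at D15.

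The list calls depended on the correlation assumed between members. With an estimated correlation 1 list was called for D15 against D5, 1 between the stages, 0 from D5 to D6, 2 from D6 to D7, 0 from D7 to D8, 2 from D8 to D10 and 0 from D10 to D15. Fry asks whether members changed in a common direction, without setting them against other genes. With it the numbers were 23, 23, 18, 13 and 14 for the first 5 of these, then 16 and 18. Neural and smooth muscle genes for D15 against D5 passed upward in fry, where camera pointed down without passing. Over 196 list results, most of them without a call, the estimated correlation lost 64 calls and left 6, and fry gained 59 and lost 4. Over all fits with a library left out, 1465 list results had the same outcome, called or not, 17 calls were gained and 30 lost. From D5 to D6 the number of lists called then ran from 6 to 12, and elsewhere it was 11 for D15 against D5 and between the stages, 7 to 9 from D6 to D7, 6 to 11 from D7 to D8, 11 to 14 from D8 to D10 and 9 to 10 from D10 to D15. The cause was not tested.

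With libraries left out in turn, genes called ran from 11517 to 11800 across days, 9967 to 10044 for D15 against D5, 10027 to 10153 between the stages, 3693 to 3982 from D5 to D6, 3237 to 3526 from D6 to D7, 2326 to 2950 from D7 to D8, 3155 to 3884 from D8 to D10 and 6011 to 6405 from D10 to D15. Of the named gene results, 1424 had the same outcome, called or not, 30 calls were lost and 4 gained. Among whole-data alternatives, RLE factors left the outcome of all 169 named results the same. DESeq2 left 164, lost 1 call and gained 3, and limma-voom left 163, lost 2 and gained 4. Without a filter 2 were lost. In fits of the compared days alone 1 was lost and 2 gained, and the stage-only model lost 1 and gained 1. The largest shift of the median fold change by scaling was 0.063 log2 units, with upper quartile factors from D10 to D15, where the share of higher genes among those called went from 52% to 44.3%, so that most calls were lower. At this depth the floor of 3 counts was 0.14 to 0.172 CPM for a day, so genes lower than that on both days have no fold here.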

Other observations

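The lists of this section (imprinted growth genes, ATF4 targets and low-oxygen targets) and the splits of whole days were chosen after the results were seen. The p-values of these lists were not adjusted over comparisons, and the bootstrap intervals resample list members, not libraries. For the imprinted list, chosen with the values in view, both describe the members and are not an independent test. Imprinted growth genes, expressed from one parental copy and active in the fetus, were higher at D6 than at D5 in 11 of 14 cases and lower in none (median 0.60, bootstrap interval 0.31 to 1.22, camera p = 4.78e-13, and 0.00261 with an estimated correlation). Plagl1, a zinc finger regulator of that network, went from 99.4 to 1849 CPM, and Igf2, a fetal growth factor, from 5095 to 11833 CPM. From D7 to D8 the same list had 8 higher and none lower (median 0.23, camera p = 8.49e-07, and 0.0243 with an estimated correlation). From D10 to D15 it had 9 lower and 2 higher (median -0.55, camera p = 1.49e-04, and 0.0706 with an estimated correlation). Peg10, derived from a retrotransposon, went from 2908 to 351 CPM there, and Mest, a hydrolase gene of mesoderm, from 969 to 341 CPM.

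Txnip and Arrdc4, singled out after the values were seen, moved the same way at each step from D5 to D10 and parted from D10 to D15. Txnip stood at 8.79, 115, 16.1, 366, 743 and 1139 CPM at D5, D6, D7, D8, D10 and D15, and Arrdc4 at 1.95, 17.8, 2.35, 48.6, 62.0 and 54.0 CPM.

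Sarcomere genes differed between libraries of the same day. In each of the 6 days their deviation fell in the order of the columns, as from 0.467 through 0.181 to -0.648 at D7, and whether that order follows cultures over the days was not given. The endothelium minus fibroblast slope was chosen after the correlations were seen, and the 6 relations were one family over 18 libraries with 46656 permutations within days, which take libraries of different days as unrelated. The labels do not settle that, and if cultures were followed over days these p-values are too small and none of the explanations is excluded. Sarcomere and fibroblast deviations went opposite ways (r = -0.842, interval -0.951 to -0.542, permutation p = 0.000686, adjusted p = 0.00412; rho = -0.787, permutation p = 0.000579; r = -0.749 without the 2 farthest libraries), which could come from another share of muscle cells. Harvest at another point of the course would move fibroblast genes, which rose over the days, with sarcomere genes, and they went the other way. Heterochronic genes went the way it would move them (r = -0.645, permutation p = 0.0408, adjusted p = 0.122, rho = -0.628, permutation p = 0.0428, r = -0.608 without 2). A trade against all other cells alike would give endothelium and fibroblast genes the same slope, and the slopes differed by 0.331 ± 0.132 (exact p = 0.0232). For library size r was 0.539 (interval -0.017 to 0.84, exact p = 0.125, adjusted p = 0.188, rho = 0.457, permutation p = 0.15, r = 0.266 without 2). With cultures perhaps followed over days, these explanations stay open.

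Most of the 6 amino acid stress genes were higher at D7 than at D6 and D8, and also higher at D5 than at D6 and at D15 than at D10. The ATF4 targets (33 genes outside the pattern) were lower at D8 than at D7 in 28 cases (median -0.789, interval -0.959 to -0.698, p = 0.00224 with an estimated correlation) and higher at D7 than at D6 in 27 (median 0.544, interval 0.367 to 0.723, p = 0.0215), which would fit an ATF4 response, perhaps to amino acid supply. They were also lower at D6 than at D5 in 22 cases (median -0.567, p = 0.0236 with an estimated correlation) and higher at D15 than at D10 in 24 (median 0.372, p = 0.157), the last of which did not pass. Whether scaling plays a part was not decided, since the other factors shifted the median of all genes from D7 to D8 by at most 0.024 log2 units and left that of the 6 genes, chosen for the pattern, at -2.241 at its smallest. Days of medium change were not given in the sources used here, so the trigger stays open.

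Of 16 glycolysis genes 12 were called higher from D7 to D8, with Slc2a1 lower, and 14 from D8 to D10, though neither list call held with an estimated correlation (adjusted p = 0.393 and 0.199). Low-oxygen targets outside glycolysis (22 genes) had a median of 1.179 from D7 to D8 (interval 0.652 to 1.473, 17 higher, p = 0.0692 with an estimated correlation) and 1.142 from D8 to D10 (interval 0.812 to 1.514, 20 higher, p = 0.05), which might reflect a low-oxygen response in denser cultures. Part of the rise at D8 came from 1 library with the highest glycolysis mean of its day. Without it the low-oxygen median from D7 to D8 was 0.895 (14 higher, p = 0.074 with an estimated correlation) and from D8 to D10 it was 1.518 (20 higher, p = 0.0271). Reads shared with pseudogenes were argued against, since 90% of glycolysis genes with at least 80% unique stretches (9 of 10) were called higher between the stages. Oxygen was not measured in the sources used here, so the cause stays open.

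Library assignments were drawn to ask how many calls arise with days exchanged. Across days, 1 of 100 assignments, the real one, called as many genes (11663, highest other 5368), so chance can be excluded if libraries are unrelated. Between the stages it was again 1 when single libraries were exchanged (10111, highest other 4758), but the stages are made of whole days, and 10 splits of the 6 days are too few for a share under 0.05 (10111, highest other 9399). For pairs of days 10 splits are too few for a share under 0.05. The real split called 10231 genes for D15 against D5 (highest other 0), 4540 from D5 to D6 (0), 3984 from D6 to D7 (1), 3168 from D7 to D8 (0), 4093 from D8 to D10 (0) and 6662 from D10 to D15 (0), each reached by 1 split alone.

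Single libraries stood out, seen after the fact. Alb, a liver gene, had 163 counts in 1 D15 library against 1 and 3 in the others, and Apoa1, of liver and gut, 34 in that library against 1 and 8. In 1 D8 library the embryonic globin genes Hba-x and Hbb-y had 48 and 47 counts, against 3 and 0 for Hba-x and 1 and 0 for Hbb-y in the others.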
